A study of Homo sapiens with 22 samples.

How the data were processed

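RNA from 6 human B-cell lymphoma lines was measured on 22 Affymetrix HG-U133A arrays, on which each transcript is read by 1 or more probe sets of short oligonucleotides. The lines were Daudi, Namalwa and Raji, derived from Burkitt lymphoma, and SU-DHL4, SU-DHL6 and HT, derived from diffuse large B-cell lymphoma (DLBCL). Each line was measured untreated and after combined treatment with 5-aza-2'-deoxycytidine (5-aza-dC), an inhibitor of DNA methyltransferases, and trichostatin A (TSA), an inhibitor of histone deacetylases. The 12 groups held 2 arrays each, except that HT had 1 array per treatment. The labels disagree on the dose of 5-aza-dC: the sample titles give 5 µM and the protocol and the series design text give 3 µM. Both give 6 days of 5-aza-dC and 625 nM TSA for the last 24 h. The dose used is therefore open, and no result below depends on it.

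The deposited values are log2 expression values that the authors made by robust multi-array averaging (RMA), which corrects background, quantile-normalizes the probes over all arrays and summarises them per probe set. R version 2.10.1 and RMA are named in the submitters' processing notes, and RMA and a moderated test in the series design text. Probe-level files were not used here. A second deposited file holds the authors' p-values, their Benjamini-Hochberg adjusted p-values and log2 differences per probe set. Its log2 differences equalled treated minus untreated means of the arrays to within 3.5e-14, although its column heading names the untreated cells first. Its p-values equalled those of limma on the 22 arrays with cell line as an additive term to within 5.1e-13. Arrays carry no read depth; their number limits the precision.

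The value table held 22283 probe sets. The 68 control probe sets (AFFX) were left out of all tests. Of the other 22215 probe sets, 19065 had 1 gene symbol in the platform annotation, 1043 had several and 2107 had none, and only the first kind was named. Of these, 19053 matched the RefSeq gene table by Entrez identifier, and 0 symbols needed an update. For each of the 11963 genes the probe set with the highest mean over all 22 arrays was used, and 4310 genes had more than 1. No filter on dim probe sets was applied. Since neither the files nor the labels name a genome build, no coordinates are given.

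Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). The effect over the 6 lines was tested on 12 values, the means of the arrays of each line and treatment, with line as a block, so that lines and not arrays were the units. The effect in each line was tested on all 22 arrays with 12 group means and 1 contrast per line. HT, with single arrays, was assumed there to vary like the other lines. The difference of the effect between Burkitt and DLBCL lines was tested on the 6 line differences, and the untreated difference on the 6 untreated line means. Spread is given as the SD over lines. Nothing in the labels says that duplicate arrays came from separate cultures, so p-values for a single line measure only the spread between these samples, which may be technical.

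Gene lists, 28 in number and with 672 of 789 memberships measured, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated per list. The rule named the 12 largest rises and 12 largest falls among genes past the threshold with the same direction in all 6 lines. It also named up to 4 members per list with the largest difference, and 11 genes fixed in advance, of which 9 had a usable probe set. In each line it named the 3 genes per direction with the largest difference among those past the threshold there. For the comparisons of Burkitt with DLBCL it named the 4 genes per direction with the smallest p, since under 3 genes passed. Each list's median was also set against 10000 random lists of the same size matched on untreated level in 20 bins. This test was chosen after the data had been seen. It drew genes singly, so correlation within a list was not taken into account.

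The tests were tested on simulated data made from the arrays' own levels and spreads. Over the 6 lines, 69 of 100 genes changed by 1 on the log2 scale and 94 of 100 changed by 2 were recovered, with 11 calls among unchanged genes. In Daudi 62 and 95 of 100 were recovered and in HT 30 and 84. For the difference of the effect between Burkitt and DLBCL lines 10 and 60 of 100 were recovered, and for the untreated difference 24 and 77. All other genes of the 11963 were left unchanged, whereas 4424 were called over the 6 lines in the data. The adjusted threshold depends on the share of changed genes, so recovery in the data can differ from these values. With 4 of 28 lists moved by 1, camera called those 4 and 0 of the 21 lists that shared no moved gene. The simulated genes varied independently, whereas estimated correlations within the measured lists reached 0.85, for proliferation. This result therefore does not show how camera's preset correlation holds for correlated genes.

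Alternatives tried were arrays as units, a block on replicate number, no line block, a filter on dim probe sets, quantile normalization, median centring, the mean of a gene's probe sets, single probe sets, a robust prior, a 2-fold threshold, and leaving out each array and each line. In tests over the lines, leaving out HT or either of its arrays gave the same fit, and each was counted as an alternative. Cyclic loess, the 3 DLBCL or 3 Burkitt lines alone, a crossed pairing and the removal of SU-DHL4 together with the second treated SU-DHL6 array were added after the data had been seen. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.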

Results

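The study's title places these arrays in work on the B-cell programme of classical Hodgkin lymphoma, a B-cell tumour whose Reed-Sternberg cells have lost most B-cell markers. The question put to these 22 arrays was which genes change when B-cell lymphoma lines are treated with a DNA methyltransferase inhibitor and a histone deacetylase inhibitor together. Of the arrays, 11 came from treated and 11 from untreated cells of 6 lines, and values are log2 RMA expression throughout. Array medians lay between 6.72 and 6.91. The interquartile range of the values was 2.32 to 2.59 on the untreated arrays. On the treated arrays it was 2.03 and 1.96 in SU-DHL4, 1.996 on the second SU-DHL6 array and 2.23 to 2.41 on the others. On that SU-DHL6 array the control probe sets for the 3' end of ACTB exceeded those for the 5' end by 2.08, against at most 0.07 on any untreated array. The matching value for GAPDH was 1.34, against at most 0.64. Both of these untreated maxima came from the second untreated Raji array, whose duplicate had -0.75 for ACTB and -0.02 for GAPDH. The next highest untreated values were -0.29 for ACTB and 0.55 for GAPDH, both on the second untreated SU-DHL6 array.

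**Figure D1:**
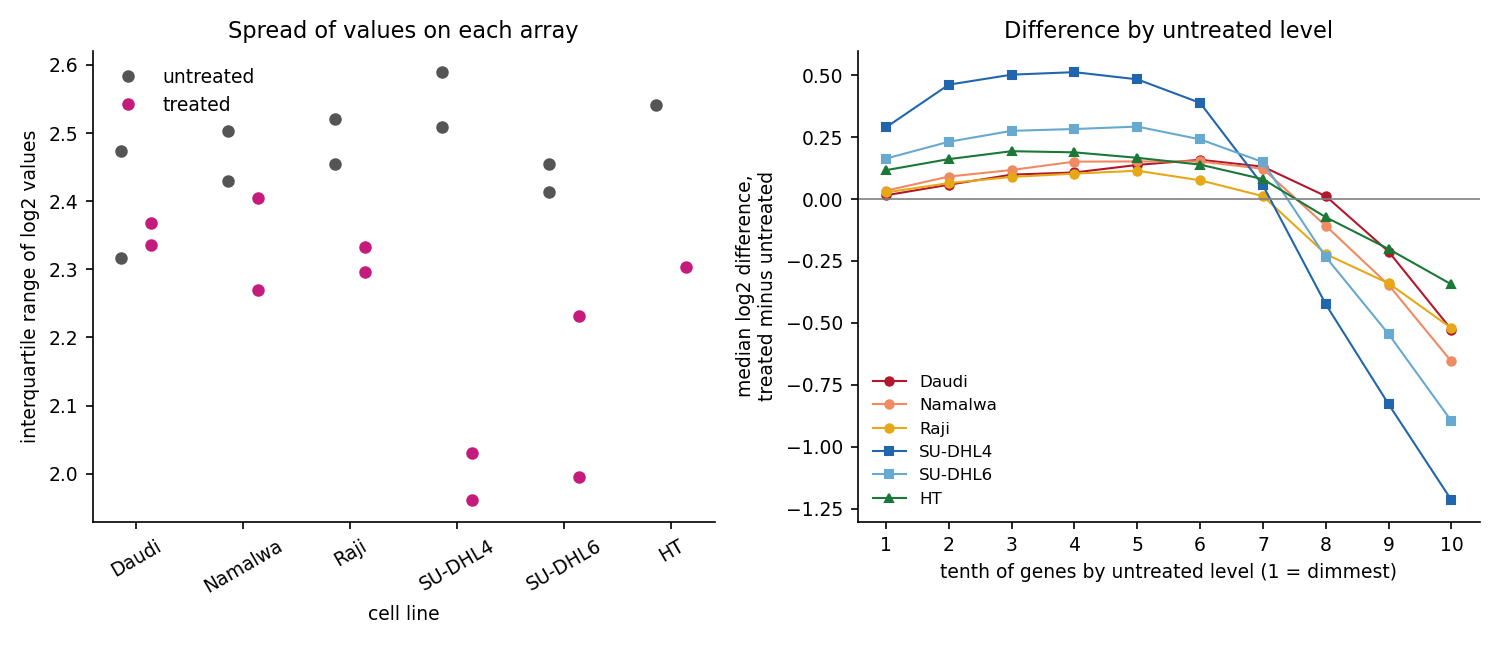
Left, the interquartile range of the log2 values of each array (1 point per array, by cell line and treatment); the treated SU-DHL4 arrays (2.03 and 1.96) and the second treated SU-DHL6 array (1.996) sit lowest. Right, the median log2 difference, treated minus untreated, in 10 groups of the 11963 genes by untreated level, 1 curve per line; over the 6 lines it was 0.12 in the dimmest group and -0.69 in the brightest.

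Treated cells lost transcripts of B-cell genes that included RGS13, POU2AF1 and CD79B, and gained transcripts of genes that included LGALS1, HSPA2 and histone genes. The largest fall over the 6 lines was in RGS13, a regulator of G-protein signalling in germinal centre B cells, at -4.02 ± 1.68 on the log2 scale (SD over 6 lines; limma adjusted p = 0.00174). On 8 of the 11 treated arrays RGS13 was at or below 5.12, among the dimmest gene values, so the size of its fall is a lower bound. The other genes among the 12 largest falls had no treated array that dim. POU2AF1, a transcriptional coactivator of B cells, fell by 3.49 ± 0.64, and BLNK, the adaptor that links the receptor to downstream signalling, by 3.35 ± 0.89. CD79B, a chain of the receptor, fell by 3.16 ± 0.38 and its partner CD79A by 3.03 ± 1.11. MYC, a driver of growth, fell by 3.25 ± 0.94. The other 6 of the 12 largest falls were JCHAIN (-2.99), PTPRC (-2.96), TYMS (-2.92), IRAG2 (-2.77), VPREB3 (-2.75) and CORO1A (-2.74). The other probe set of TYMS, which encodes thymidylate synthase, gave 0.01.

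The largest rise was in LGALS1, which encodes the carbohydrate-binding protein galectin-1, at 3.996 ± 1.11 (SD over 6 lines; limma adjusted p = 0.000434). HSPA2, a heat shock protein of male germ cells, rose by 3.74 ± 0.93 and TKTL1, a transketolase-like gene, by 3.63 ± 1.57. DHRS2 rose by 3.28 ± 1.09, the histone gene H2BC5 by 3.18 ± 0.81 and TXNIP, which binds thioredoxin, by 3.17 ± 0.36. SERPINI1 (2.87), NEU1 (2.86), CCNA1 (2.81), H2BC21 (2.70), CDKN1C (2.70) and TUFT1 (2.68) completed the 12 largest rises. CCNA1, a cyclin of germ cells, had the widest spread of the 12, with an SD of 2.78 over the lines and an adjusted p of 0.0440. Of the called genes named here, 42 had another probe set, which in 10 of them gave no call in the same direction.

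**Figure D2:**
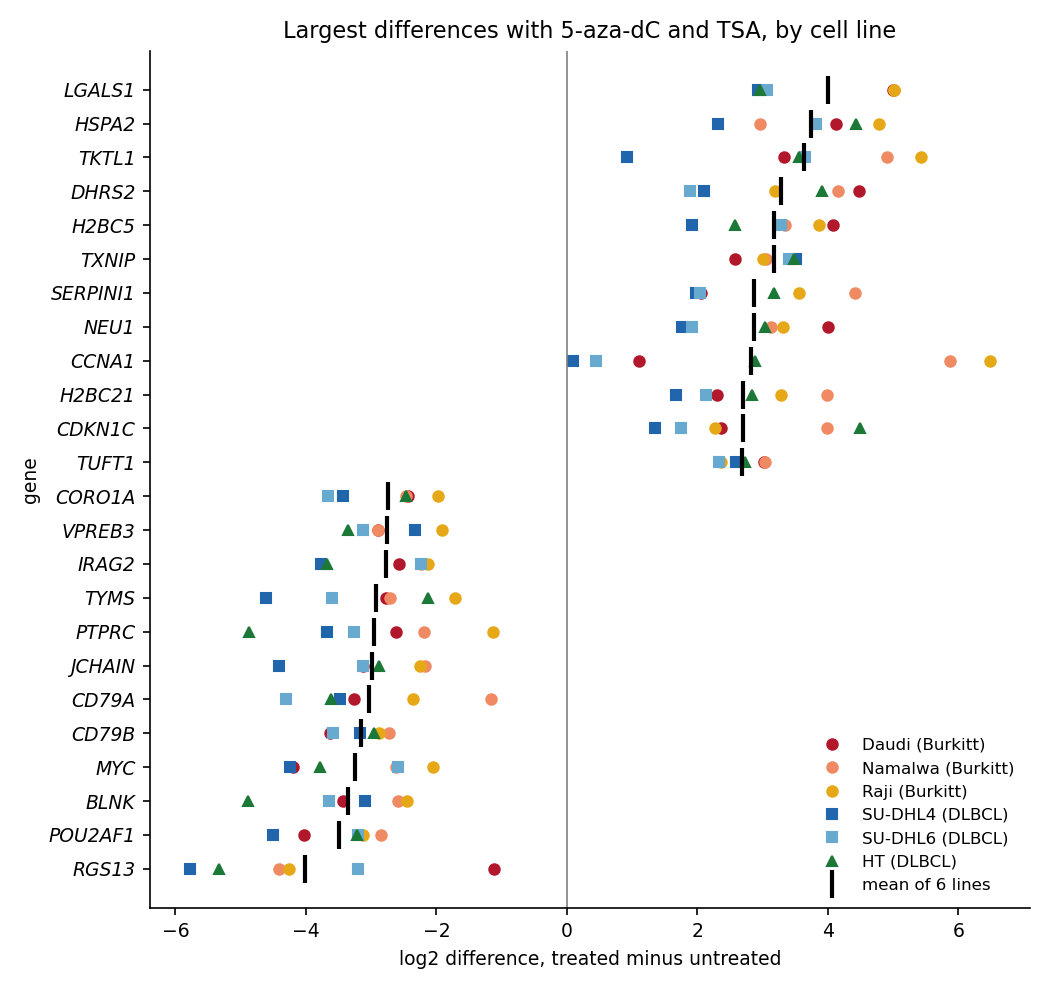
The log2 difference, treated minus untreated, of the 12 genes that rose most and the 12 that fell most, with 1 point per cell line and a bar at the mean of the 6 lines. All 6 lines lie on the same side of 0 for each gene, as the naming rule required; LGALS1 had the highest mean, 3.996, and RGS13 the lowest, -4.02.

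Of 11963 genes, limma called 2238 higher and 2186 lower in treated cells, of which 310 and 927 differed by 2-fold or more. Among the 4424 called genes, 3853 had the same sign in all 6 lines, and over all tested genes 41.8% did, against 3.12% by chance for independent signs. Without SU-DHL4 and the second treated SU-DHL6 array, an alternative added after seeing the data, 1737 were higher and 1743 lower, 3269 of them among the 4424. Without Namalwa 1429 were higher, and without SU-DHL6 1224. The median gene lay 0.12 above 0. With each array centred on its median that shift was 0.02, and 1269 genes were called higher and 2434 lower, so the share of higher calls went from 50.6% to 34.3%. The series design text names the treated Burkitt arrays as published before, so array batch can coincide with treatment in those 3 lines. The 3 DLBCL lines alone gave 469 genes higher and 986 lower, and the Burkitt lines alone 531 and 1004. Signs were also compared between the kinds of line, on the mean of the 3 lines of each kind, a comparison added after seeing the data. Of the 1455 genes called in the DLBCL lines alone, 1415 had the same sign in the Burkitt mean (97.3%). Of the 1535 called in the Burkitt lines alone, 1495 had the same sign in the DLBCL mean (97.4%). Over all genes 79.5% did.

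Genes of B-cell identity fell more often than they rose. Of 30 measured members 0 rose, 22 fell and 8 did not pass, with 2 higher and 22 lower when adjusted over the list alone. POU2AF1, BLNK, CD79B and CD79A led the list. PAX5, the transcription factor that maintains the B-cell programme, fell by 2.28 ± 0.81 (limma adjusted p = 0.00106), with its other probe set at 0.18, and MS4A1, which encodes CD20, fell by 1.86 ± 1.20. The list was called lower by camera (adjusted p = 4.16e-11), a call that was lost at an adjusted p = 0.326 with an estimated correlation. Of 18 germinal centre genes 0 rose, 12 fell and 6 did not pass (0 higher and 14 lower when adjusted over the list alone). Besides RGS13, IRAG2 fell by 2.77 ± 0.75, CD27, a receptor of the tumour necrosis factor family, by 2.72 ± 0.29, and TCL1A, an activator of AKT kinases, by 2.52 ± 0.39. Camera called this list lower (adjusted p = 1.44e-08), which became an adjusted p = 0.326 with an estimated correlation.

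Of 9 immunoglobulin genes 0 rose, 5 fell and 4 did not pass, and 0 were higher and 5 lower when adjusted over the list alone. IGLC1 fell by 2.48 ± 1.07, IGHM by 2.41 ± 1.97 and IGKC by 1.86 ± 0.77, while IGLL1 averaged -1.53 ± 2.20 without passing. The list median was 0.29 in SU-DHL4 and -0.56 to -1.90 in the other 5 lines. Some dimmer probe sets of IGLC1, IGHM and IGKC lay above 0, by at most 0.24. None of the other IGKC probe sets passed, at -0.40 to 0.08, so its fall rests on 1 probe set. Camera gave an adjusted p = 0.0176, and an adjusted p = 0.535 with an estimated correlation. After cyclic loess, also added after seeing the data, it was 0.0666, the highest of 37 alternatives, whose lowest was 0.00523.

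Plasma cell genes moved both ways. Of 22 members 6 rose, 8 fell and 8 did not pass (8 higher and 8 lower when adjusted over the list alone). JCHAIN, which joins polymeric antibodies, CD27, TNFRSF17, the receptor BCMA, at -2.44 ± 1.53, and FKBP11, a chaperone of the secretory pathway, at -1.97 ± 0.56, led the list, and all 4 fell. IRF4, a transcription factor of activated B cells and plasma cells, rose by 1.24 ± 0.94 (limma adjusted p = 0.0195; higher in 5 of 6 lines). PRDM1, the regulator of plasma cell differentiation, averaged 0.34 ± 0.29 without passing (adjusted p = 0.0582). The list's median was 0.21, its mean -0.39 and its camera direction lower, with no call (adjusted p = 0.374; adjusted p = 0.706 with an estimated correlation).

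Genes typical of Hodgkin Reed-Sternberg cells rose more often than they fell. Of 47 members 21 rose, 3 fell and 23 did not pass, with 23 higher and 3 lower when adjusted over the list alone. After LGALS1, the chemokine CCL5 rose by 2.38 ± 2.25, the chemokine receptor CCR7 by 2.35 ± 1.16 and JUN, a subunit of the AP-1 transcription factor, by 2.29 ± 0.67. ID2, an inhibitor of the B-cell factor E2A, rose by 2.16 ± 0.66 in 6 of 6 lines (limma adjusted p = 0.000636). TNFRSF8, which encodes CD30, rose by 0.30 ± 0.16. In the groups of genes nearest to TNFRSF8 in untreated level the median difference was 0.23 and 0.24, so most of its rise was shared with them. Camera called the list higher (adjusted p = 0.000871), against an adjusted p = 0.533 with an estimated correlation.

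Interferon response genes differed between lines. Of 40 members 8 rose, 0 fell and 32 did not pass (7 higher and 0 lower when adjusted over the list alone). CXCL10, an interferon-induced chemokine, rose by 2.46 ± 1.78 and IRF7, an interferon regulatory factor, by 2.35 ± 1.30, whereas IFI27 averaged 2.55 ± 3.25 and IFIT1 1.92 ± 2.79 without passing. The list median was 2.20 in Namalwa, 2.54 in Raji and -0.43 in Daudi, and lay between 0.29 and 0.34 in the DLBCL lines. Camera called the list higher (adjusted p = 0.0142), against an adjusted p = 0.706 with an estimated correlation. The call was lost without Raji (adjusted p = 0.128), without Namalwa (0.0579) and in the DLBCL lines alone (0.0692), and over 37 alternatives the adjusted p ran from 8.05e-05 to 0.128. Fry, a limma test outside these 37 that does not compare a list with other genes, made no call (adjusted p = 0.202). NF-kB targets had 10 of 29 members higher, 3 lower and 16 not passing, with 11 higher and 3 lower when adjusted over the list alone. IER3, an early response gene, rose by 1.90 ± 1.10 and LTB, which encodes lymphotoxin beta, fell by 1.94 ± 1.05. That list had no camera call (adjusted p = 0.0717, and adjusted p = 0.706 with an estimated correlation), but passed in 11 of 37 alternatives. Among them were cyclic loess (0.0136), quantile normalization (0.0354), without SU-DHL6 (0.00884) and without HT (0.0403). Leaving out HT or either of its arrays was the same fit, counted each time. The list's adjusted p ran from 0.000117 in the Burkitt lines alone to 0.817 in the DLBCL lines alone.

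The antigen presentation lists were not called over the 6 lines. Of 12 MHC class II genes 0 rose, 1 fell and 11 did not pass (0 and 0 when adjusted over the list alone). HLA-DOB fell by 0.86 ± 0.75, HLA-DQA1 averaged -0.59 ± 1.70, HLA-DMB -0.43 ± 0.91 and CIITA, the class II transactivator, 0.30 ± 0.26, its other probe sets being below 0. The list's median was 0.02, its mean -0.10 and its camera direction lower (adjusted p = 0.676; adjusted p = 0.887 with an estimated correlation). It was called higher in the Burkitt lines alone (median 0.69, adjusted p = 0.0307) and lower in the DLBCL lines alone (median -0.71, adjusted p = 0.000596), and its adjusted p was at most 0.990 in 37 alternatives. Of 13 MHC class I presentation genes 0 rose, 3 fell and 10 did not pass, with 0 higher and 2 lower when adjusted over the list alone. The immunoproteasome subunits PSMB10 and PSMB8 fell by 2.28 ± 0.65 and 1.22 ± 1.13, TAPBP averaged -1.24 ± 1.32 with its other probe set at 0.30, and HLA-E averaged 0.81 ± 0.92. This list's median of 0.22 also differed in sign from its mean of -0.21 and its camera direction, lower (adjusted p = 0.596; adjusted p = 0.887 with an estimated correlation).

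Most genes of cell division and growth fell. Of 46 proliferation genes 0 rose, 35 fell and 11 did not pass (0 higher and 39 lower when adjusted over the list alone). After TYMS, CCNA2, a cyclin of S phase and mitosis, fell by 2.30 ± 0.75, MAD2L1, of the spindle checkpoint, by 2.18 ± 1.06, and KIF11, a spindle motor, by 2.17 ± 1.33. The list median was -2.77 in SU-DHL4 and -2.09 in SU-DHL6, but -0.39 in Raji. The treated SU-DHL4 arrays and the second treated SU-DHL6 array had interquartile ranges of 1.96 to 2.03, and that SU-DHL6 array a 3' minus 5' value of 2.08 for ACTB. Across genes the second treated Raji array had a slope of 0.524 on the mean effect of the other lines, against 0.934 for the first. Camera called the proliferation list lower (adjusted p = 1.38e-13), against an adjusted p = 0.518 with an estimated correlation. Of 34 MYC targets and ribosome biogenesis genes 2 rose, 29 fell and 3 did not pass, with the same 2 and 29 counts when adjusted over the list alone. Besides MYC itself, HSPE1, a mitochondrial chaperonin, fell by 2.12 ± 0.59, NME1, a nucleoside diphosphate kinase, by 2.11 ± 0.89 and MRTO4, a ribosome assembly factor, by 2.06 ± 0.53. Camera called that list lower (adjusted p = 2.48e-13), against an adjusted p = 0.496 with an estimated correlation.

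The targets of the drugs belong to a list of chromatin and DNA methylation enzymes, of which 8 of 35 members rose, 14 fell and 13 did not pass (9 higher and 17 lower when adjusted over the list alone). DNMT1, the maintenance DNA methyltransferase, fell by 1.497 ± 0.79 and EED, of the Polycomb repressive complex, by 1.31 ± 0.63, the latter with its other probe set at -0.08 (adjusted p = 0.424). The histone demethylase gene KDM5B rose by 1.44 ± 0.56, with another probe set at 0.23. MBD2, a reader of methylated DNA, fell by 2.00 ± 0.82 on its brightest probe set, while its other 3 probe sets gave 0.17 to 0.24, 1 of them past the threshold (adjusted p = 0.0450). Camera called the list lower (adjusted p = 0.0195), against an adjusted p = 0.496 with an estimated correlation. The call was lost with dim probe sets left out (0.0792), after quantile normalization (0.0858) and after cyclic loess (0.113), and in the other alternatives was at least 0.0128.

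Cell-cycle inhibitors and p53 targets rose in 8 and fell in 3 of 25 members, with 14 not passing and the same 8 and 3 counts when adjusted over the list alone. CDKN1C, the inhibitor p57, and GADD45B (1.22 ± 0.38) rose, and CDKN1A, the inhibitor p21, rose by 1.01 ± 1.01 in 5 of 6 lines (limma adjusted p = 0.0476). The exception, SU-DHL6, rested on 1 array: its untreated arrays had 8.56 and 11.37 for CDKN1A, and its treated arrays 9.38 and 9.33. BAX, a promoter of apoptosis, fell by 1.44 ± 0.32 and CDKN2A by 1.25 ± 0.46, with 1 of its other probe sets at 0.23. Camera made no call (adjusted p = 0.244; adjusted p = 0.706 with an estimated correlation).

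Of the called genes of the germ line and of neurons all rose. Of 29 cancer-testis and germline genes, which few normal tissues outside the testis transcribe, 13 rose, 0 fell and 16 did not pass (17 higher and 1 lower when adjusted over the list alone). After TKTL1, MAGEA6 rose by 1.99 ± 1.35, MAGEA12 by 1.78 ± 0.78 and SSX1 by 1.48 ± 0.67, the last with its other probe set at 0.00 when rounded. The median untreated level of the list was 5.18, near the dimmest gene values (5.12 or below), so the sizes of some rises may be lower bounds. Camera called the list higher (adjusted p = 0.00072), against an adjusted p = 0.510 with an estimated correlation. Of 32 neuronal genes 16 rose, 0 fell and 16 did not pass, with the same 16 and 0 counts when adjusted over the list alone. NPTX2, a neuronal pentraxin, rose by 2.30 ± 1.37, KIF5C, a kinesin of axons, by 1.42 ± 0.37, CHGB, of secretory granules, by 0.92 ± 0.67 and NEFH, a neurofilament chain, by 0.82 ± 0.28. Camera called the list higher (adjusted p = 3.3e-05), against an adjusted p = 0.376 with an estimated correlation. Medians of both lists, 0.44 and 0.42, lay above all or nearly all of 10000 random lists matched on untreated level (percentile 100).

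Histone, metallothionein and TSA-inducible genes rose more often than they fell. Of 13 histone genes with polyadenylated or replication-independent transcripts 8 rose, 2 fell and 3 did not pass (9 higher and 2 lower when adjusted over the list alone). H2BC5 and H2BC21 were followed by H1-2 at 2.58 ± 1.17 and H2AC6 at 2.34 ± 0.996. Camera gave an adjusted p = 0.0187, and an adjusted p = 0.535 with an estimated correlation. Of 8 metallothioneins, which bind metal ions, 6 rose, 0 fell and 2 did not pass (7 higher and 0 lower when adjusted over the list alone). MT1X rose by 1.84 ± 0.81, MT2A by 1.61 ± 0.90, MT1H by 1.47 ± 0.70 and MT1G by 1.34 ± 0.67. Camera gave an adjusted p = 0.0036, and an adjusted p = 0.518 with an estimated correlation. Of 25 cytoskeletal and vesicle genes listed as inducible by butyrate and TSA 12 rose, 0 fell and 13 did not pass (15 higher and 0 lower when adjusted over the list alone). The tubulin genes TUBB2A and TUBB2B rose by 2.04 ± 2.00 and 1.88 ± 1.79, SAT1, of polyamine breakdown, by 1.65 ± 0.62 and SQSTM1, an autophagy receptor, by 1.52 ± 0.81. Camera gave an adjusted p = 0.00221, and an adjusted p = 0.496 with an estimated correlation.

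Most myeloid, epithelial and mesenchymal genes did not pass. Of 22 myeloid markers 5 rose, 0 fell and 17 did not pass, of 19 epithelial genes 5 rose, 0 fell and 14 did not pass, and of 27 fibroblast and mesenchymal genes 5 rose, 0 fell and 22 did not pass. Adjusted over the list alone, 5, 5 and 3 rose and 0 fell. CSF1R, a receptor of macrophage growth factor, rose by 1.17 ± 0.50, CEBPA by 0.86 ± 0.45 and AIF1 by 0.50 ± 0.26, and CST3 averaged 1.18 ± 1.36. The junction genes JUP and DSP rose by 1.22 ± 0.71 and 0.97 ± 0.49, ELF3 by 0.70 ± 0.36 and KRT18 by 0.64 ± 0.49. FN1, which encodes fibronectin, rose by 1.32 ± 0.63, the collagen genes COL6A1 and COL6A3 by 0.78 ± 0.23 and 0.64 ± 0.35, and VIM averaged 1.21 ± 1.88. None of the 7 other COL6A1 probe sets passed, at -0.15 to 0.28. Camera called the myeloid (adjusted p = 0.0239), epithelial (0.0368) and mesenchymal (0.0316) lists higher, each lost at an adjusted p = 0.515, 0.515 and 0.518 with an estimated correlation. These calls also ended after quantile normalization (0.209, 0.223 and 0.172), after cyclic loess (0.241, 0.272 and 0.265, the highest of 37 alternatives) and when SU-DHL4 and the second treated SU-DHL6 array were left out together (0.0590, 0.0594 and 0.0601). The lowest were 0.00835, 0.0178 and 0.0162. Without Namalwa or Raji the epithelial (0.0506 and 0.0571) and mesenchymal (0.0506 and 0.0540) calls ended. The epithelial call also ended after median centring (0.0504), without HT (0.0505), the first treated (0.0538) or first untreated (0.0570) Daudi array, or the second untreated SU-DHL6 array (0.0516). In the Burkitt lines alone the myeloid (0.0840) and epithelial (0.0595) calls ended. Their medians of 0.19, 0.19 and 0.21 lay at percentiles 63.2, 52.9 and 70.3 of random lists matched on untreated level.

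T-cell markers, with 7 of 20 higher, 1 lower and 12 not passing, and NK and cytotoxic markers, with 3 of 16 higher, 0 lower and 13 not passing, were not called; adjusted over the list alone, the counts were 7 and 1, and 3 and 0. LCK, a kinase of lymphocytes, fell by 2.05 ± 0.84. GATA3 rose by 0.75 ± 0.31, with its other probe sets at 0.13 and 0.08, neither passing. CTLA4 rose by 0.48 ± 0.38, GZMK by 0.47 ± 0.28 and PRF1 by 0.43 ± 0.30, while TRBC1 averaged -0.68 ± 1.34, KLRB1 0.42 ± 0.48 and NCR3 0.40 ± 0.47. Camera gave an adjusted p = 0.0545 for T-cell markers (adjusted p = 0.606 with an estimated correlation) and an adjusted p = 0.0677 for NK markers (adjusted p = 0.606 with an estimated correlation). T-cell markers passed in 10 of 37 alternatives, which ran from 0.0383 without Daudi to 0.195 after cyclic loess. Single arrays whose absence let them pass were the second untreated Daudi (0.0468), the second treated (0.0448) and first untreated (0.0464) Namalwa, the first treated (0.0465) and second untreated (0.0484) Raji and the first treated SU-DHL6 array (0.0456). NK markers passed in 4 alternatives, including without Daudi (0.0383), its second untreated array (0.0495) or the first treated SU-DHL6 array (0.0456), and had 0.513 after cyclic loess.

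Stress and metabolic genes moved both ways. Of 24 genes of endoplasmic reticulum stress 7 rose, 6 fell and 11 did not pass (9 higher and 6 lower when adjusted over the list alone), with ATF3 at 1.88 ± 0.99 and SEL1L at 1.08 ± 0.34, both higher, and ATF4 at -1.03 ± 0.60 and SDF2L1 at -0.96 ± 0.49, both lower. Its median of -0.08 and mean of 0.03 differed in sign, and camera's direction was lower (adjusted p = 0.678; adjusted p = 0.887 with an estimated correlation). Of 16 heat shock proteins 6 rose, 6 fell and 4 did not pass, with the same counts when adjusted over the list alone. HSPB1 rose by 2.08 ± 1.06 and BAG3 by 1.68 ± 0.73. The median of 0.14 and mean of 0.18 lay above 0 and camera's direction was lower (adjusted p = 0.760; adjusted p = 0.887 with an estimated correlation). Of 19 cholesterol synthesis genes 4 rose, 6 fell and 9 did not pass (5 higher and 6 lower when adjusted over the list alone). FDPS fell by 1.73 ± 0.52, MSMO1 by 1.21 ± 0.95 and HMGCS1 by 1.02 ± 0.97, and TM7SF2 rose by 1.17 ± 0.70 (camera adjusted p = 0.270; adjusted p = 0.706 with an estimated correlation). Of 26 apoptosis regulators 3 rose, 4 fell and 19 did not pass (1 higher and 3 lower when adjusted over the list alone). BID fell by 1.46 ± 0.53 and FADD by 0.70 ± 0.17, and BCL2A1 averaged 0.98 ± 1.65 (camera adjusted p = 0.298; adjusted p = 0.669 with an estimated correlation). Of 16 imprinted genes 4 rose, 2 fell and 10 did not pass, with the same counts when adjusted over the list alone. NNAT rose by 0.75 ± 0.17, SGCE fell by 0.77 ± 0.45 and PEG10 averaged 1.33 ± 1.58 (camera adjusted p = 0.340; adjusted p = 0.606 with an estimated correlation).

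In all, camera called 10 of the 28 lists higher and 6 lower, and 0 and 0 with an estimated correlation. Since the median difference was below 0 in bright and above 0 in dim genes, each median was also set against random lists matched on untreated level. The B-cell identity, germinal centre and proliferation medians lay at percentile 0, MYC targets at 0.01, immunoglobulin genes at 0.16 and chromatin enzymes at 1.54. The Hodgkin Reed-Sternberg, histone, metallothionein, interferon and TSA-inducible medians lay at percentile 100. Of the lists that camera did not call, NF-kB targets lay at percentile 100, MHC class I at 99.9 and MHC class II at 98.3, above the ranges of their matched lists. Plasma cell (97.4) and cell-cycle and p53 genes (97.46) lay just inside their ranges, and the other 7 uncalled lists lay at 13.9 to 90.6. The random lists drew genes singly, whereas estimated correlations within lists reached 0.76 for interferon, 0.69 for metallothionein and 0.85 for proliferation genes. For such lists the percentiles are too extreme.

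**Figure D3:**
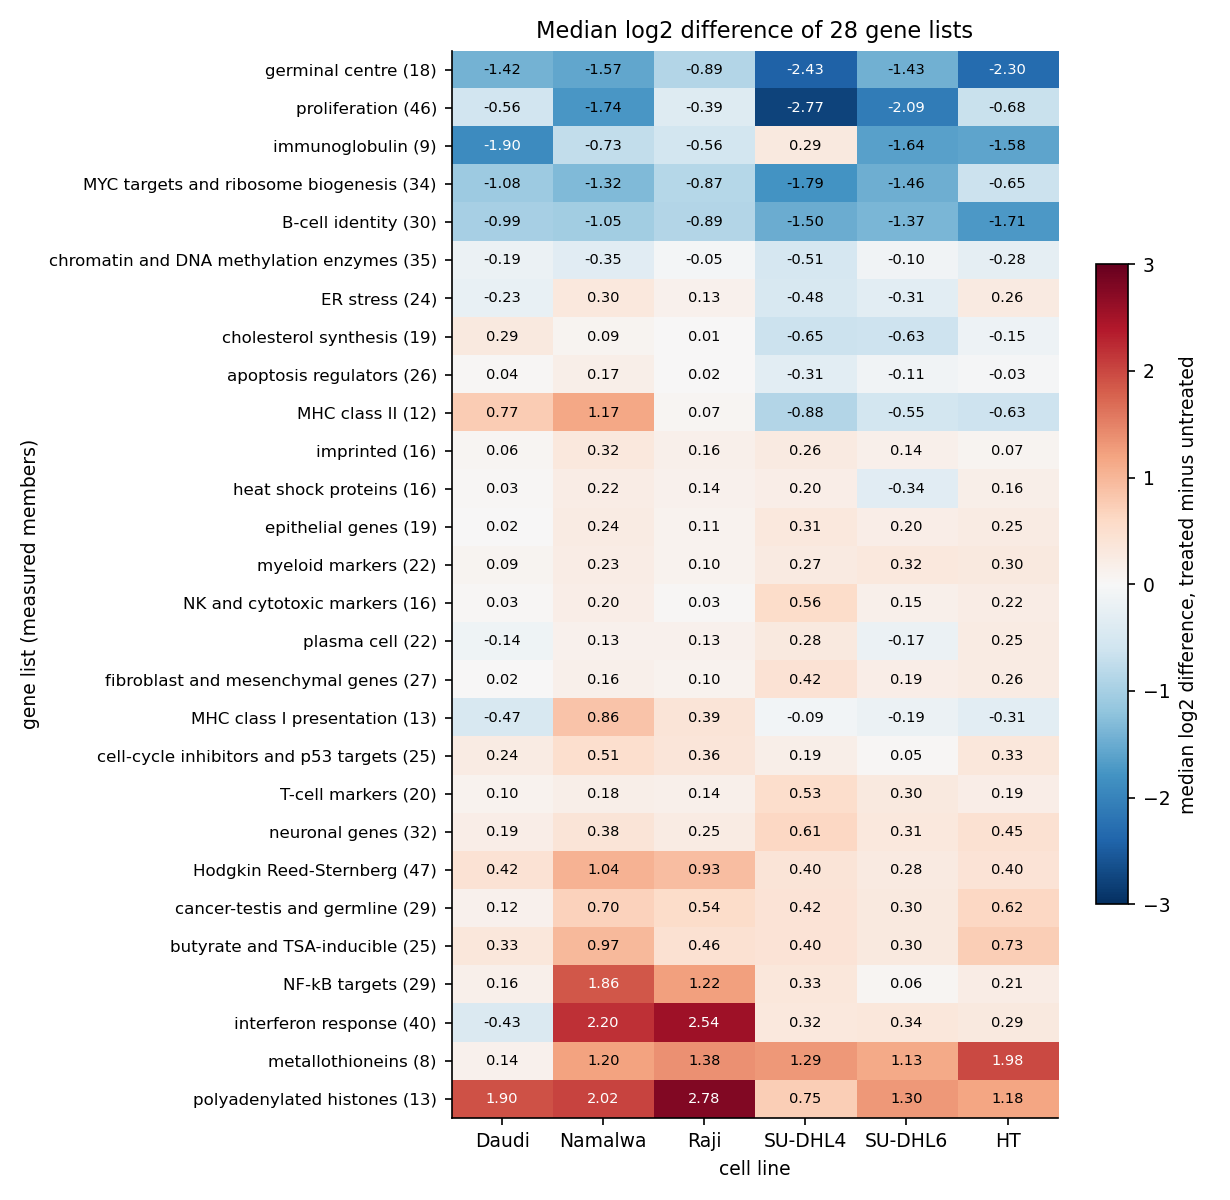
The median log2 difference, treated minus untreated, of each of the 28 gene lists (measured members in brackets) in each of the 6 cell lines, in colour and as a number. The germinal centre list was below 0 in all 6 lines; the interferon list was 2.20 in Namalwa and 2.54 in Raji, and -0.43 in Daudi.

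Each line was also tested by itself. Daudi responded most in LGALS1 (5.00), DHRS2 (4.48) and HSPA2 (4.12), which rose, and in MYC (-4.21), the receptor gene GPR18 (-4.15) and POU2AF1 (-4.02), which fell. In Namalwa the interferon-induced gene IFI27 (6.96), CCNA1 (5.86) and the protease inhibitor CSTA (5.30) rose most, and RGS13 (-4.41), the transcription factor BACH2 (-3.72) and the importin IPO5 (-3.34) fell most. In Raji CCNA1 (6.48), the chemokine CXCL11 (6.23) and IFI27 (6.09) rose most, and RGS13 (-4.27), SPARCL1 (-3.54) and POU2AF1 (-3.13) fell most. Without the first treated Raji array RGS13 had -2.68 and POU2AF1 -1.41, and without the second POU2AF1 had -4.85. SU-DHL4 gained TXNIP (3.51), the desaturase SCD5 (3.09) and LGALS1 (2.92) and lost RGS13 (-5.78), the mitotic kinase PBK (-4.97) and the chromatin protein HMGB2 (-4.78), and SCD5 had 1.87 without the first untreated array. SU-DHL6 gained HSPA2 (3.82), TKTL1 (3.65) and the Notch target HES1 (3.58) and lost TNFRSF17 (-4.33), CD79A (-4.31) and IGHM (-3.88). HT gained CDKN1C (4.49), HSPA2 (4.43) and TUBB2B (4.19) and lost IGLL1 (-5.36), RGS13 (-5.33) and BLNK (-4.89). All of these genes were picked among those past limma's adjusted threshold in their line, so that they passed is not a result. The spread behind the p-values of each line was pooled over lines. In HT, with 1 array per treatment, it came from the other lines alone, and Raji tested by itself had 6 calls in place of 1891.

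In Daudi 1293 genes were called higher and 1222 lower, in Namalwa 1307 and 1583, in Raji 671 and 1220, in SU-DHL4 4257 and 2881, in SU-DHL6 1912 and 2011, and in HT, with 1 array per treatment, 264 and 300. In each of the 6 lines 54 genes were called higher and 109 lower, and 335 genes were called in opposite directions in different lines. Pearson's r of the differences between pairs of lines ran from 0.543 to 0.797 across genes, which are not independent replicates. Numbers of calls depended on single arrays. Daudi had 1306 to 1666 calls without any 1 of its 4 arrays, and Namalwa 1713 and 1821 without its first or second untreated array. Raji had 761 without its first treated and 996 without its second untreated array. SU-DHL6 had 2237 without its second treated array, the one with the high 3' to 5' values, and as many without its first untreated array. HT had 883 without either treated Raji array.

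The next question, whether Burkitt and DLBCL lines responded alike, was answered gene by gene on the line differences. LGALS1 rose by 5.01 ± 0.00 in the 3 Burkitt lines and by 2.99 ± 0.08 in the 3 DLBCL lines (SD over lines), a difference of 2.02 (SE 0.14; limma adjusted p = 0.0348) and the only one that passed. Untreated Burkitt lines held less LGALS1, at 6.40 ± 0.10 against 8.44 ± 0.55, so that treated levels differed by -0.02. Effect and untreated level share the untreated arrays. The genes with the next smallest p did not pass: the integrin gene ITGAL (1.81, adjusted p = 0.188), NFKB2, of the NF-kB family (2.42, 0.188), and the kinase LYN (1.59, 0.203) had higher differences in Burkitt lines. YBX3 (-1.38, 0.188), PLAC8 (-3.08, 0.305), WASF3 (-1.54, 0.333) and PRKAR2B (-3.22, 0.333) had lower ones. ITGAL and LYN fell in the DLBCL lines, so their higher differences stand for a fall that was smaller or absent in Burkitt lines. On the untreated DLBCL arrays WASF3 was at 5.23 to 5.46, PRKAR2B at 4.98 to 5.88 and PLAC8 at 5.50 to 6.26. The dimmest gene values were 5.12 or below, so little fall could show there. In all 1315 genes had an unadjusted p under 0.05. The call for LGALS1 was lost without HT, after quantile normalization or cyclic loess, with a robust prior and with dim probe sets left out, while 1484 genes passed with arrays as units. It was also lost without the first treated Daudi, first treated Raji, either treated or the first untreated SU-DHL4, or the second treated or either untreated SU-DHL6 array.

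**Figure D4:**
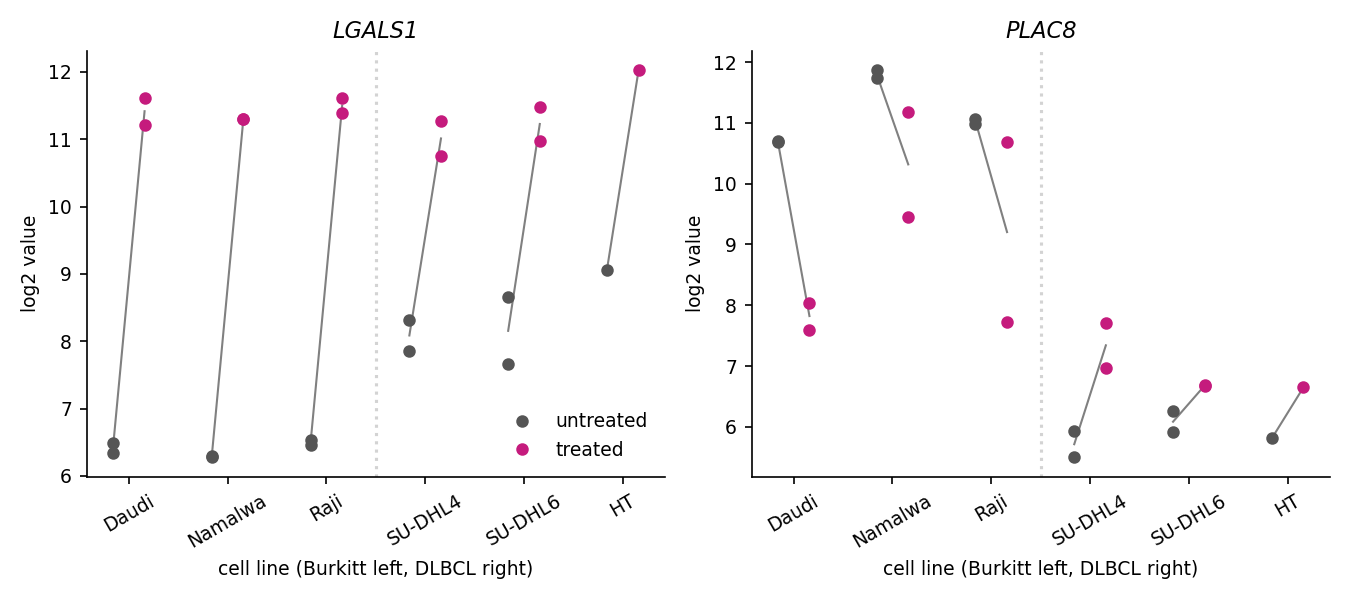
Log2 values of LGALS1 and PLAC8 on each array (points), untreated and treated, with a line between the means of the arrays, in 3 Burkitt and 3 DLBCL lines. LGALS1 means rose by 5.01 in Burkitt and 2.99 in DLBCL lines; untreated PLAC8 was 11.2 in Burkitt and 5.87 in DLBCL lines.

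Before treatment, PLAC8 was the only gene that passed between Burkitt and DLBCL lines. It was at 11.18 ± 0.57 in Burkitt and 5.87 ± 0.19 in DLBCL lines (SD over 3 lines each), a difference of 5.31 (SE 0.30, limma adjusted p = 0.0436). AFF1 (3.19, adjusted p = 0.137), THEMIS2 (1.48, 0.137) and the activation marker CD69 (1.87, 0.237) had higher untreated levels in Burkitt lines without passing. On the untreated DLBCL arrays AFF1 was at 4.92 to 5.48 and CD69 at 4.62 to 5.17. These are near the dimmest gene values, so the sizes of both differences may be lower bounds. ZNF331 (-0.68, 0.256), PLEKHF2 (-1.34, 0.359), SH2B2 (-1.25, 0.359) and LGALS1 (-2.04, 0.359) had lower ones. There were 649 genes at an unadjusted p under 0.05. Without HT, the second untreated Namalwa, the second untreated SU-DHL4 or the first untreated SU-DHL6 array 0 genes passed in limma. The labels give no batch for the untreated arrays or for the DLBCL arrays, so a batch could not be taken into account in either comparison.

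The authors' deposited table, which took arrays as units, had 12677 of 22283 probe sets at an adjusted p under 0.05, 7707 of them positive and 4970 negative. Of the 4424 genes called over the lines here, 4415 had an adjusted p under 0.05 and the same sign on the same probe set in the authors' deposited table, and 2870 more genes passed there alone. For LGALS1 the authors' deposited table gave a difference of 4.09, for RGS13 -3.90, for ID2 2.23 and for PRDM1 0.34.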

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

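The tests of array range, RNA quality, kind of lymphoma and batch, and the list tests between Burkitt and DLBCL lines, were chosen after the result was seen; the splits of the samples were chosen before.

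In 5 of 150 results, which were 122 named genes and 28 list medians, 1 cell line lay far from the other 5 by Dixon's ratio. Chance does this in about 1 in 20 groups, or 7.5 of the 150. NCR3 was 1.29 in SU-DHL4, MT2A was -0.11 in Daudi and MBD2 was -3.59 in SU-DHL4. The median of the NK and cytotoxic list was 0.56 in SU-DHL4, and that of the heat shock list -0.34 in SU-DHL6.

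The effect of treatment on LGALS1 differed by 2.02 between Burkitt and DLBCL lines. Of the 10 splits of the 6 lines into 3 and 3, only 1, the real one, gave 1 gene, and the highest of the others gave 0; 10 splits are too few for a share under 0.05. The untreated comparison, with PLAC8 as its 1 gene, also had 1 of 10 splits and a highest other of 0, with the same limit.

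Set tests with camera on the difference of the effects called 17 lists, 16 of them higher in Burkitt lines, and 0 with an estimated correlation (smallest adjusted p = 0.213). The median difference was 1.31 for MHC class II, 1.26 for interferon response, 1.12 for NF-kB targets, 1.04 for histones, 0.88 for proliferation and 0.87 for germinal centre genes. It was 0.70 for MHC class I presentation, 0.68 for Hodgkin Reed-Sternberg, 0.497 for cholesterol synthesis, 0.46 for B-cell identity, 0.39 for heat shock proteins and 0.35 for TSA-inducible genes. For apoptosis regulators it was 0.31, for MYC targets 0.29, for cell-cycle inhibitors and p53 targets 0.28, for endoplasmic reticulum stress 0.20 and for metallothioneins -0.56. In germinal centre, B-cell, proliferation, MYC target and cholesterol synthesis genes a positive value stands for a smaller fall in Burkitt lines. Some lists had medians above 0 in Burkitt and below 0 in DLBCL lines. These were MHC class II (0.69 and -0.71), MHC class I presentation (0.11 and -0.38), apoptosis regulators (0.12 and -0.11) and endoplasmic reticulum stress (0.21 and -0.22). On the untreated levels, whose arrays the effects share, camera called 8 lists, 6 higher in Burkitt lines, and 0 with an estimated correlation (smallest adjusted p = 0.608). The median difference there was 1.06 for MHC class I presentation, 0.501 for interferon response, 0.29 for NF-kB targets, 0.26 for plasma cell, 0.21 for endoplasmic reticulum stress and 0.13 for Hodgkin Reed-Sternberg genes, and -0.37 for germinal centre and -0.13 for proliferation genes.

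The interferon and NF-kB genes had higher differences in the Burkitt than in the DLBCL lines. For interferon genes, both the kind of lymphoma and a batch acting alike on the treated arrays of the 3 Burkitt lines are argued against as the only source by Daudi, where the median was -0.43, with -0.58 and -0.36 on its arrays, against 0.29 in the lowest DLBCL line. For NF-kB genes both stay open and cannot be told apart, since Daudi had 0.16 and the DLBCL lines 0.06 to 0.33, and the labels give no batch for the other arrays. A narrower array range in the DLBCL lines is argued against by the gap between the kinds of line for both lists pooled, 69 genes, which was 1.05 after cyclic loess and 0.99 before. Differences between single lines, and a batch that acted on some of the Burkitt arrays only, were not tested.

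On the control probe sets, which no comparison used, the 3' minus 5' value exceeded all untreated arrays on 3 treated arrays. The second SU-DHL6 array had 1.34 for GAPDH and 2.08 for ACTB, the first SU-DHL6 array 0.47 for ACTB and the second SU-DHL4 array 0.28 for ACTB, where untreated arrays reached 0.64 and 0.07. Those 2 untreated values came from 1 array, the second untreated Raji array. On the other untreated arrays ACTB reached -0.29, and further treated arrays exceeded that, among them the first SU-DHL4 array (0.07) and the HT array (0.01). Among 3150 probe sets without a single gene symbol, 825 were called over the 6 lines, 461 higher and 364 lower.

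The median difference was above 0 in dim and below 0 in bright genes, and the treated arrays had a narrower range of values. For the myeloid, epithelial and mesenchymal lists together this range could account for the rise, since their median of 0.20 lay within the 0.12 to 0.24 of random lists matched on untreated level. It is argued against as the whole source of the rise of neuronal, cancer-testis and Hodgkin genes (0.425 against 0.12 to 0.22) and of the fall of B-cell and germinal centre genes (-1.35 against -0.59 to -0.07). The random lists drew genes singly, so these limits ignore correlation within the lists and are too narrow for genes that move together. Loss of 5' signal as the source of the narrower range stays open with 6 lines, at Spearman's rho -0.714 for GAPDH (exact permutation p = 0.136, adjusted 0.272) and -0.771 for ACTB (p = 0.103, adjusted 0.272). Pearson's r was -0.512 (permutation p = 0.285, adjusted 0.285) and -0.600 (p = 0.207, adjusted 0.276), and -0.970 and -0.102 without the 2 lines farthest out, so the ACTB value rests on those lines; no biological explanation of the range was tested.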

How the results depend on the processing

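Cyclic loess, the removal of SU-DHL4 with the second treated SU-DHL6 array, the crossed pairing, and the DLBCL or Burkitt lines alone were chosen after the result was seen. Of 122 named genes 106 were called over the 6 lines. In the alternatives that followed single genes all 106 kept their direction and 47 their call, but these genes were chosen on the same arrays. Single probe sets and the 2-fold threshold were not followed by gene. Of the called genes 9 had another probe set in the opposite direction, in 1 of them past the threshold. For counts that moved, the cause was not tested, except where arrays stood in for lines as units, more probe sets were tested, the threshold was raised, or lines or arrays were left out. The number of arrays limits the precision.

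Genes higher over the 6 lines numbered 2238, and 4446 with arrays as units and a line block, 4912 as the average of 6 line contrasts, 3864 with arrays as units and a replicate block, 1269 after median centring, 3473 by probe set and 310 at a 2-fold threshold. They numbered 469 in the DLBCL lines alone and 531 in the Burkitt lines alone. Genes lower, 2186, became 3720 by probe set, 927 at 2-fold, and 986 and 1004 in the DLBCL and Burkitt lines alone. Leaving out 1 array or line gave 1224 (without SU-DHL6) to 2489 higher, with 1429 without Namalwa, and 1657 to 2291 lower. Quantile normalization gave 1889 and 1707, cyclic loess 1967 and 1836, a filter on dim probe sets 1827 and 2149, and no line block 2122 and 1878. The median gene lay 0.12 above 0 in the deposited values, and 0.08, 0.02 and 0.04 after quantile normalization, median centring and cyclic loess.

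By probe set Daudi, Namalwa, Raji, SU-DHL4, SU-DHL6 and HT had 4024, 4606, 2870, 12579, 6278 and 867 calls, and at 2-fold the first 5 had 1380, 1626, 1055, 2910 and 1637. Tested by itself, Raji had 6 calls and SU-DHL6 1502. Leaving out 1 array gave 1306 to 2867 calls in Daudi, 1713 to 3244 in Namalwa, 761 to 2359 in Raji, 5246 to 7453 in SU-DHL4, 2237 to 5152 in SU-DHL6 and 449 to 883 in HT, where lone arrays were assumed to vary like the others. The replicate numbers did not pair the arrays: the correlation of treated and untreated deviations across genes ran from -0.116 to 0.026. A crossed pairing gave 2366 calls in Daudi and 2738 in Namalwa, against 2200 and 2552 with a block on the replicate numbers as given.

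The 1 gene of the difference in effect between Burkitt and DLBCL lines became 1484 with arrays as units and 989 with arrays as units and a replicate block. It became 0 in limma with dim probe sets left out, quantile normalization, a robust prior, cyclic loess or without HT, and 0 to 1 without single arrays. The 1 gene of the untreated comparison became 2 by probe set, 0 without HT, and 0 to 1 without single arrays. Before these changes 1315 and 649 genes had an unadjusted p under 0.05.

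Gene lists called higher, 10, became 0 with an estimated correlation, 8 after quantile normalization or cyclic loess, and 7 to 12 without single arrays or lines. Lists called lower, 6, became 0 with an estimated correlation 10 in the DLBCL lines alone, 5 after quantile normalization or with dim probe sets left out and 4 after cyclic loess, and stayed at 6 without any array or line. Fry, which does not compare a list with other genes, called 12 higher and 7 lower. It did not call interferon response (adjusted p = 0.202), which camera called, but did call the plasma cell, T-cell, NK and imprinted lists. The MHC class II list, not called over the 6 lines with a camera direction of lower and a median of 0.02, was called higher in the Burkitt lines alone (median 0.69, adjusted p = 0.0307). In the DLBCL lines alone MHC class I (0.0440), cholesterol (0.0172), apoptosis (0.0426), T-cell (0.0426) and NK (0.0426) lists passed, as did cell-cycle and p53 genes in the Burkitt lines alone (0.0181), where the myeloid (0.0840) and epithelial (0.0595) calls ended.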

Other observations

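The tests of gene families and of the weaker Raji array were chosen after the result was seen; the splits of the samples were chosen before.

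Most genes of the mitochondrial ribosome fell in treated cells. Of 31 MRPL genes, which encode proteins of its large subunit, 26 fell and 0 rose (median -1.14, camera adjusted p = 4.41e-13; adjusted p = 0.735 with an estimated correlation). Of 20 MRPS genes, of the small subunit, 16 fell and 0 rose (median -1.22, adjusted p = 2.91e-10; adjusted p = 0.735 with an estimated correlation). MRPL23 fell by 2.13 ± 0.40 (SD over 6 lines), MRPL15 by 1.95 ± 0.69 and MRPL3 by 1.93 ± 0.52. The 51 genes had a median of -1.14, against -0.68 to -0.17 for random lists matched on untreated level. Those lists drew genes singly and so ignore correlation within the set. Of 21 NUP genes, mostly nucleoporins, 14 fell and 0 rose (median -0.83, adjusted p = 7.92e-06; adjusted p = 0.735 with an estimated correlation). Of 18 CCL chemokine genes 6 rose and 0 fell (median 0.34, adjusted p = 0.0398; adjusted p = 0.735 with an estimated correlation). Families were taken from 81 shared symbol stems of at least 15 genes, of which 11 were called lower and 7 higher, with 5 and 1 also outside the range of matched random lists, and 0 with an estimated correlation.

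The second treated Raji array had a weaker response than its duplicate, with a slope of 0.524 against 0.934 on the mean effect of the other 5 lines, across genes. A narrower range of that array is argued against, since its interquartile range exceeded that of its duplicate by 0.0376. Interferon genes ran the other way, with a median of 3.23 on this array and 1.60 on its duplicate, and their pooled median with NF-kB genes was 2.17 against 1.43. Admixture of untreated RNA or cells would lower these genes too, so it is argued against as the only difference between both arrays and stays open for the other genes. A share of 34.8%, fitted on 985 genes that fell in the other lines, gave 1.11 for 325 rising genes, where the array had 0.71. The gap was 0.40. Both sets were limited to genes called over the 6 lines, so Raji helped to choose them. A weaker treatment was not tested.

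Of 100 splits drawn from the 462 splits of the 12 line means, only 1, the real one, gave as many genes as the 4424 called. The highest other gave 1460. With line as a block, a line with both means on 1 side adds nothing to the effect, so such splits test chance weakly. Among the 32 splits that part every line's treated and untreated mean, only 1, the real one, gave as many genes. The highest other of these gave 0 at the adjusted threshold in limma. This argues against chance for the count, but not against an array batch that coincides with treatment. For the number of gene lists called, 18 of the 100 splits gave 16 or more and the highest other gave 22, so chance cannot be excluded for it. Among the 32 splits that part every line, 7 gave as many lists and the highest other gave 20.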
